A study of Salmo salar with 2 samples.

How the data were processed

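Nuclei of control (untreated) Atlantic salmon fin skin were measured by droplet-based 3′ single-nucleus RNA sequencing in 2 libraries, with 1 library per group. Groups were taken from the labels only: library 3 carries a title that names dorsal fin and pectoral together and forms a group of its own, and library 4 is pectoral fin. Of the 2 titles only that of library 4 carries the word control. Per the labels' protocols, skin was cut up in TST buffer to release nuclei, which were loaded with an aim of 7000 per library. No further libraries, treatments or time points were analysed here. The groups, comparisons, gene lists and the rule for named genes were set before the data were examined.

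The values deposited by the authors are unnormalized UMI counts per gene and barcode, made with STAR 2.7.10a per the submitters' processing notes. The genome build, the annotation release, the counting of intronic reads and the treatment of reads that match several genes are not given in the sources used here. Each deposited table lists 69264 genes, 30391 of them with a symbol, and 6794880 barcodes, so it was not filtered for nuclei. Library 3 holds 932455 barcodes with a UMI and library 4 holds 1479508. Mitochondrial genes could not be recognised by name, so no filter on them was applied.

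Everything below was computed from those counts. The rule fixed in advance for calling nuclei, based on the 99th percentile of UMIs among the top 7000 barcodes divided by 10, gave 1161 UMIs in library 3 and 951 UMIs in library 4. In library 4 that value lies inside the peak of droplets without a nucleus and would have taken 47658 barcodes. It was replaced after the UMI histograms were seen by the mode of that peak plus 3 SD on the log10 scale, with at least 300 genes, giving 851 and 1577 UMIs. The called nuclei held 39.0% and 41.1% of all UMIs of their library. Scrublet called 0 nuclei as doublets in either library (score thresholds of 0.604 and 0.66), so it did not work here and doublets may remain. Free RNA was measured as the mean profile of 51015 and 37835 droplets without a nucleus, within 2 SD of the mode, with a mean of 484 and 1096 UMIs. For the values called subtracted, the mean profile times the number of nuclei was taken from each sum.

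Nuclei of both libraries were clustered together with scanpy 1.11.5 in Python 3.11.15 (anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9). Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were ranked within each library with every gene of the readout lists left out, and 30 components, 15 neighbours and a Leiden resolution of 1.0 were used. Clusters were named from 29 marker lists where at least 3 list genes stood 2-fold above all nuclei of the library, with at least 30 nuclei of the cluster in the library. These genes could be no fewer than the other detected list genes, and the mean log2 ratio of the list had to reach 1.0. Keratinocyte-like clusters without a clear layer did not have to meet this. In clusters 0, 1 and 6 of that kind 0 of 17 detected epithelial genes stood 2-fold above. Further naming rules were made after the clusters were seen. Clusters with markers of several lineages (8, 10 and 13, 1894 nuclei) were clustered again, which raised the number of clusters from 17 to 41, and limits of 0.75 and 1.0 on a ratio of epithelial markers separated keratinocytes from other lineages. A class held by different clusters in the libraries was compared only where a check of the top 10 genes passed in both. It passed where no list of another lineage had more genes among them than the lists of the class's own lineage. In the superficial and mucous cell-like clusters 0 genes of any list were among the top 10. The check was met there without saying anything of their identity. It left out the keratinocyte-like remainder, since notch3 was among the top genes of its cluster 6. Sums of some lists are still given for that remainder in both libraries.

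UMIs were summed per class and library and divided by the summed UMIs of all genes to give CPM. Intervals are at 95%: exact Poisson for sums, conditional exact binomial for ratios and Clopper-Pearson for shares. Where a library had 0 counts the fold was computed against a floor of 3 counts and is given as at least that fold, and no fold is given where both libraries lie at or under the floor. Nuclei of a library are not replicates of the fin, so no test between libraries was run and no number of changed genes is given. For the lists between libraries, the median log2 ratio over members with at least 10 UMIs was placed among 10000 random lists of the same size, matched on expression in 20 bins. Scaling by trimmed mean of M values used edgeR 4.0.16 in R 4.3.3, as an alternative only. Nuclei were thinned to 1500 UMIs for the share with cell cycle genes, a depth that followed from the thresholds used.

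Genes were named by a rule: for a class, the 3 most abundant of its markers that are 2-fold above other nuclei. Between libraries they were the 3 symbols with the largest ratio each way, with at least 50 CPM in the higher library and 50 UMIs over both, in all nuclei and in named classes with at least 200 nuclei in both libraries (basal and superficial keratinocyte-like). Fin patterning genes needed 20 CPM in a named class with at least 200 nuclei in a library, which took in fibroblast-like and endothelial-like nuclei of library 3, with at most 12 given. For each readout list they were the 3 most abundant members where the list peaked and the 3 with the largest ratio between basal and superficial nuclei that went the same way in both libraries, with at least 20 UMIs in each. Ribosomal protein genes were used only as a sum.

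The intervals and the subtraction were tested on simulated counts drawn from the real means, with 200 changed genes. Counts were drawn with counting error only, and the free RNA added was the profile later subtracted. The check thus covers the computation and not how well these assumptions hold in the data. Calling, clustering and naming were not simulated. Intervals of the fold between libraries in a simulated class held the truth for 96.2% of 17889 unchanged genes. They did so for 92.0%, 96.0%, 94.0% and 96.0% of 50 genes each changed by 1.5-fold, 2-fold, 4-fold and 10-fold, and left out a ratio of 1 for 58.0%, 86.0%, 100% and 100% of them. Subtraction left 8.4% and 5.7% of the RNA of 40 genes simulated as free RNA only. Alternatives covered the calling rule, doublets, clustering settings, sub-clustering, scaling, low filters, free RNA, the summary of a list and the definition of cycling nuclei.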

Results

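Nuclei from the fin skin of untreated Atlantic salmon (Salmo salar) were profiled with a droplet-based 3′ kit that tags each captured transcript with a unique molecular identifier (UMI). There were 2 libraries with 1 library per group: library 3, whose title names dorsal fin and pectoral together and is used here as it stands, and library 4, from pectoral fin. Library 3 held 45638997 UMIs and library 4 held 88539982. A total of 7573 nuclei were called in library 3, with a median of 1559 UMIs and 1091 genes, and 13155 in library 4, with a median of 2362 UMIs and 1452 genes. RNA outside nuclei, measured in droplets without a nucleus, made up an estimated 20.6% of the UMIs of called nuclei in library 3 and 39.6% in library 4. Without replicate libraries no difference between the libraries could be tested, and every comparison between them is of these libraries and not of the fins. All intervals are exact 95% intervals covering counting error only.

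**Figure D1:**
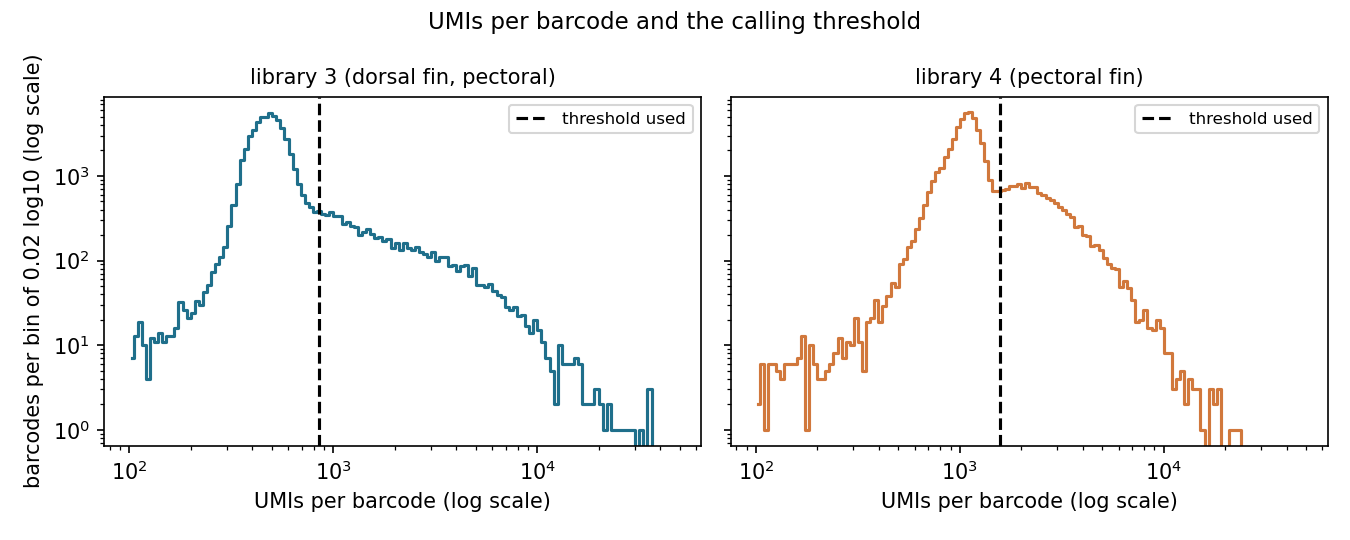
Barcodes (y axis, log scale, per bin of log10 UMIs) against UMIs per barcode (x axis, log scale) in each library, with the threshold used for calling nuclei as a dashed line. The peak of droplets without a nucleus lies at 480.5 UMIs in library 3 and at 1094 UMIs in library 4, and the thresholds lie at 851 and 1577 UMIs.

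The first question was which cell types the skin of each library held. Keratinocyte-like nuclei, the epithelial cells of fish skin, formed the largest group, with 51.7% (50.6 to 52.9) of library 3 and 95.5% (95.1 to 95.9) of library 4, and connective tissue made up a far larger share of library 3. Fibroblast-like nuclei made up 24.3% (23.3 to 25.2) of library 3 and 1.32% (1.13 to 1.52) of library 4. They were marked by col1a1b (ENSSSAG00000069947) and both copies of col1a2 (ENSSSAG00000067809 and ENSSSAG00000046988), the chains of type I collagen. Endothelial-like nuclei, marked by egfl7 (ENSSSAG00000083641), flt4 (ENSSSAG00000084309) and TIE1 (ENSSSAG00000079214) of blood and lymph vessels, made up 5.96% (5.43 to 6.51) and 0.82% (0.67 to 0.99). Mucous cell-like nuclei, marked by SPDEF (ENSSSAG00000074163), a transcription factor of goblet cells, by agr2 (ENSSSAG00000073304), which helps mucins fold, and by galnt6 (ENSSSAG00000049562), which adds sugars to them, made up 3.76% (3.35 to 4.22) and 0.78% (0.64 to 0.95).

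Basal keratinocyte-like nuclei, marked by DST (ENSSSAG00000077926), ITGA6 (ENSSSAG00000006725) and LAMA3 (ENSSSAG00000078246), which anchor basal cells to the basement membrane, made up 15.9% (15.1 to 16.7) of library 3 and 11.8% (11.2 to 12.3) of library 4. DST reached 2212 CPM (counts scaled to library depth) in this class, against 682 CPM in all other nuclei. Superficial keratinocyte-like nuclei made up 9.28% (703 nuclei) and 12.4% (1634 nuclei). They were named from 3 of only 4 matched markers, both copies of ppl (ENSSSAG00000003101 and ENSSSAG00000118293) and evpla (ENSSSAG00000048370), which encode periplakin and envoplakin of the cell envelope. A further 26.6% (25.6 to 27.6) and 71.3% (70.5 to 72.1) were keratinocyte-like without a clear layer. In this remainder only ovol1 (ENSSSAG00000084654), a regulator of epithelial differentiation, of the 21 epithelial list genes stood 2-fold above other nuclei. It was named largely by exclusion and was not compared between libraries gene by gene.

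Smaller classes followed. Macrophage-like nuclei, marked by the scavenger receptor MARCO (ENSSSAG00000063051) and both copies of CSF1R (ENSSSAG00000061479 and ENSSSAG00000047020), numbered 194 and 6. Osteoblast-like nuclei, marked by both copies of col10a1b (ENSSSAG00000114656 and ENSSSAG00000067854), a collagen of mineralising tissue, and by entpd5a (ENSSSAG00000004925), numbered 105 and 76. T cell-like nuclei with runx3 (ENSSSAG00000064246) and both copies of BCL11B (ENSSSAG00000045088 and ENSSSAG00000071984), transcription factors of T cells, numbered 102 in library 3 and 0 in library 4, where 0 of 13155 allows a share of up to 0.03% by counting alone, although a separate cluster of fewer than 30 nuclei in library 4 would have stayed unnamed. Skeletal muscle-like nuclei, led by both copies of TTN (titin, ENSSSAG00000119643 and ENSSSAG00000095939) and by neb (nebulin, ENSSSAG00000080313), numbered 31 and 0. Another 8.58% (7.96 to 9.24) and 0.95% (0.79 to 1.13) stayed unnamed. Among them was a cluster of 52 nuclei of library 3 with 5 of 8 detected leukocyte markers 2-fold above all nuclei of that library. A naming rule set after the data were seen kept it from a leukocyte-like name, since its ratio of epithelial markers was 1.85.

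The calling thresholds of 851 and 1577 UMIs can shape these shares: among the 3734 nuclei of library 3 past the threshold of library 4, 14.3% (13.2 to 15.5) were fibroblast-like. Most classes were held by different clusters in the 2 libraries (fibroblast-like mostly by cluster 3 in library 3 and by parts of cluster 13 in library 4). Across the other settings the fibroblast-like share ran from 10.6% to 47.1% in library 3 and from 0.03% to 6.26% in library 4, with library 3 higher at each setting, the basal share from 0 to 20.2% and from 0 to 13.9%, and the superficial share from 1.77% to 11.6% and from 0 to 20.2%, and the endothelial-like (at most 6.68% and 1.13%) and mucous cell-like shares (at most 4.52% and 1.21%) fell to 0 in each library at a setting or more.

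**Figure D2:**
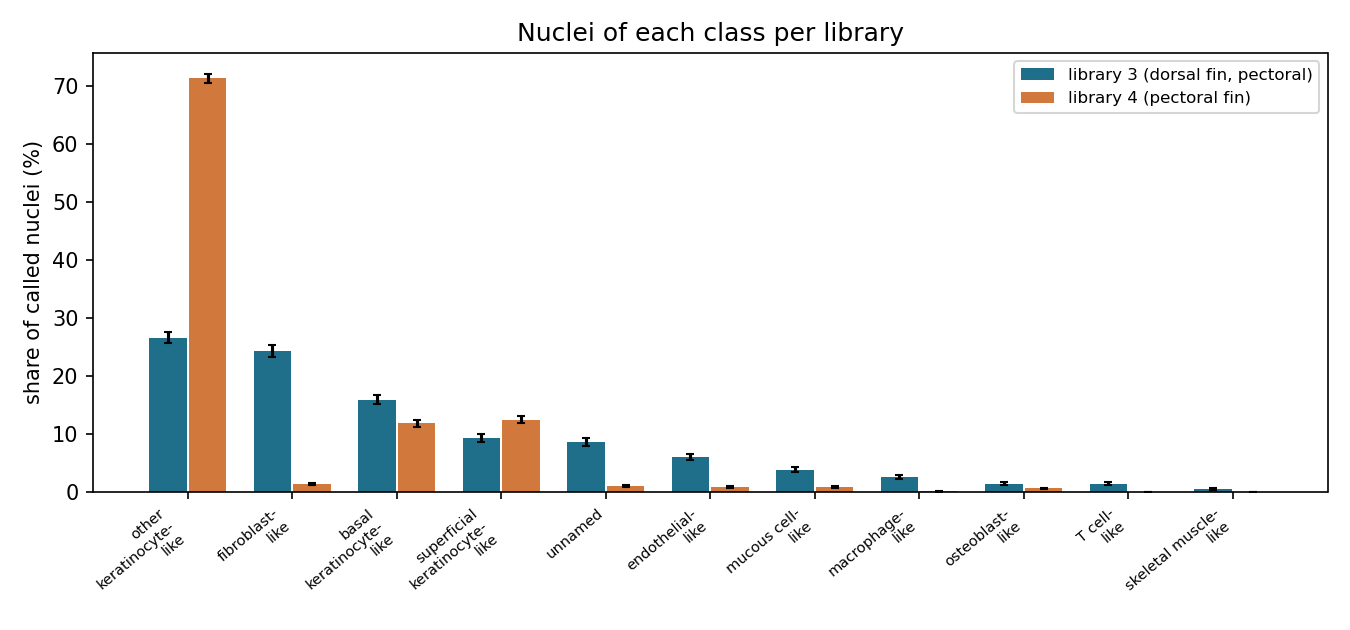
Share of called nuclei (y axis, percent) in each class, by library, with error bars as exact 95% intervals for counting error. Fibroblast-like nuclei reach 24.3% in library 3 and 1.32% in library 4, and keratinocyte-like nuclei without a clear layer 26.6% and 71.3%.

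The series concerns skin cells in transition, so 11 gene lists of growth, signalling and stress were compared between basal and superficial keratinocyte-like nuclei, the inner and outer ends of the epidermis. Genes of epithelial-mesenchymal transition and matrix remodelling were higher in basal nuclei, 5.34-fold (5.05 to 5.66) in library 3 and 2.25-fold (2.16 to 2.34) in library 4. Hedgehog pathway genes were 5.81-fold (5.09 to 6.66) and 3.35-fold (2.99 to 3.75) higher in basal nuclei, and genes of TGF-beta and BMP signalling 2.25-fold (2.15 to 2.36) and 1.55-fold (1.49 to 1.61). Wnt genes were 1.77-fold (1.70 to 1.85) and 1.27-fold (1.22 to 1.32) higher in basal nuclei. Interferon and inflammation genes went the other way, 1.75-fold (1.67 to 1.83) and 1.60-fold (1.55 to 1.66) higher in superficial nuclei.

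The members behind these sums mostly moved together. Of 29 genes of the transition and matrix list with at least 20 UMIs in each library, 23 were higher in basal nuclei of both libraries and 2 in superficial nuclei of both. Among them were mmp11b (ENSSSAG00000063600), a matrix metalloproteinase, at 15.98-fold (10.9 to 24.3) in library 3 and 3.61-fold (2.86 to 4.599) in library 4. Its copy mmp11a (ENSSSAG00000069747) stood at 10.6 CPM in basal against 0.71 CPM in superficial nuclei of library 3 and at 6.67 against 1.40 CPM in library 4. CDH2 (N-cadherin, ENSSSAG00000079622) was higher in basal nuclei at 6.45-fold (3.81 to 11.7) and 4.61-fold (2.84 to 7.80). All 11 Hedgehog genes with that many UMIs were higher in basal nuclei of both libraries, with the transcription factor gli1 (ENSSSAG00000046547) at 5.22-fold (2.81 to 10.6) and 4.39-fold (2.30 to 9.07). The co-receptors boc (ENSSSAG00000076978) and cdon (ENSSSAG00000086667) were higher by 5.57-fold and 4.77-fold in library 3 and by 4.03-fold and 3.98-fold in library 4. In the TGF-beta and BMP list 23 of 27 genes were higher in basal nuclei of both libraries, led by a copy of ltbp1 (ENSSSAG00000003342), which stores TGF-beta in the matrix, at 19.7-fold (14.1 to 28.3) and 4.28-fold (3.39 to 5.44). The other copy of ltbp1 (ENSSSAG00000044896) was higher by 9.25-fold and 2.72-fold, and smad7 (ENSSSAG00000105197), an inhibitor of the pathway, by 3.20-fold and 3.46-fold.

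In the Wnt list 34 of 46 genes were higher in basal nuclei of both libraries and 5 in superficial nuclei of both. The receptor ror2 (ENSSSAG00000088840) was 7.12-fold (4.08 to 13.5) and 3.46-fold (2.51 to 4.85) higher in basal nuclei, and rnf43 (ENSSSAG00000073513), which removes Wnt receptors, 5.48-fold (3.36 to 9.43) and 3.36-fold (2.33 to 4.96). The transcription factor tcf7l1b (ENSSSAG00000076151) stood against the list, 10.0-fold (6.94 to 14.9) and 9.62-fold (7.40 to 12.7) higher in superficial nuclei. Among 32 interferon and inflammation genes 23 were higher in superficial nuclei of both libraries and 6 in basal nuclei of both. The cyclooxygenase copy ptgs2b (ENSSSAG00000076453) was 4.04-fold (2.52 to 6.72) and 3.08-fold (2.37 to 4.06) higher in superficial nuclei, and tlr3 (ENSSSAG00000040910), a sensor of viral RNA, 3.02-fold (1.36 to 7.39) and 2.34-fold (1.56 to 3.57). The copy ptgs2a (ENSSSAG00000005275) went the other way, 2.21-fold (0.81 to 6.94) and 2.38-fold (1.23 to 4.84) higher in basal nuclei.

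Further lists differed little as sums while single members differed strongly. Notch genes were 1.1-fold (1.02 to 1.19) and 1.201-fold (1.13 to 1.28) higher in basal nuclei. In contrast the ligand gene dlc (ENSSSAG00000047939) was 12.7-fold (6.84 to 26.0) and 4.94-fold (3.14 to 8.08) higher in superficial nuclei, its other copy (ENSSSAG00000069926) 11.3-fold and 1.82-fold, and the ligand gene jag1b (ENSSSAG00000009193) 2.27-fold and 1.81-fold higher in basal nuclei. FGF genes were 1.27-fold (1.19 to 1.36) and 1.14-fold (1.08 to 1.21) higher in basal nuclei. There fgfr3 (ENSSSAG00000103995), a receptor, was 8.84-fold (7.03 to 11.2) and 2.699-fold (2.30 to 3.18) higher in superficial nuclei, as was spred1 (ENSSSAG00000008025), which restrains the pathway, by 2.51-fold and 2.30-fold. Another such inhibitor, spry1 (ENSSSAG00000073660), was 3.88-fold and 3.38-fold higher in basal nuclei. Fin patterning genes summed to 1.35-fold (1.29 to 1.42) and 1.14-fold (1.08 to 1.2) more in superficial nuclei. Here meis2 (ENSSSAG00000001608) was 3.66-fold (3.33 to 4.04) and 2.03-fold (1.85 to 2.23) higher in superficial nuclei, while hoxc6a (ENSSSAG00000065777) was 2.96-fold and 1.48-fold, and meis2a (ENSSSAG00000007719) 1.22-fold and 1.41-fold, higher in basal nuclei.

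Immediate early and heat shock genes stood at 3076 CPM in basal and 3007 CPM in superficial nuclei of library 3 (ratio 1.02, 0.99 to 1.05) and at 5218 and 5004 CPM in library 4 (1.04, 1.03 to 1.06). In this list ddit3 (ENSSSAG00000103408), a stress transcription factor, was 3.70-fold and 2.44-fold higher in superficial nuclei. JUND (ENSSSAG00000084562) and dnajb1b (ENSSSAG00000084756), an AP-1 subunit and a chaperone, were higher in basal nuclei by 2.45-fold and 2.56-fold in library 3 and by 2.01-fold and 1.82-fold in library 4. Ribosomal protein genes were 1.32-fold (1.30 to 1.33) and 1.15-fold (1.15 to 1.16) higher in basal nuclei. As the mean log2 CPM per gene the transition and matrix ratio was 2.18 in library 3 and 1.47 in library 4 and the Hedgehog ratio 2.10 and 1.58; with free RNA subtracted they were 9.89 and 4.29, and 8.77 and 5.31. Without the gene with the most UMIs in each list the fin patterning ratio of basal over superficial nuclei turned to 1.28 and 1.22, the FGF ratio of library 3 turned to 0.897, and the Notch ratio of library 3 turned as well.

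**Figure D3:**
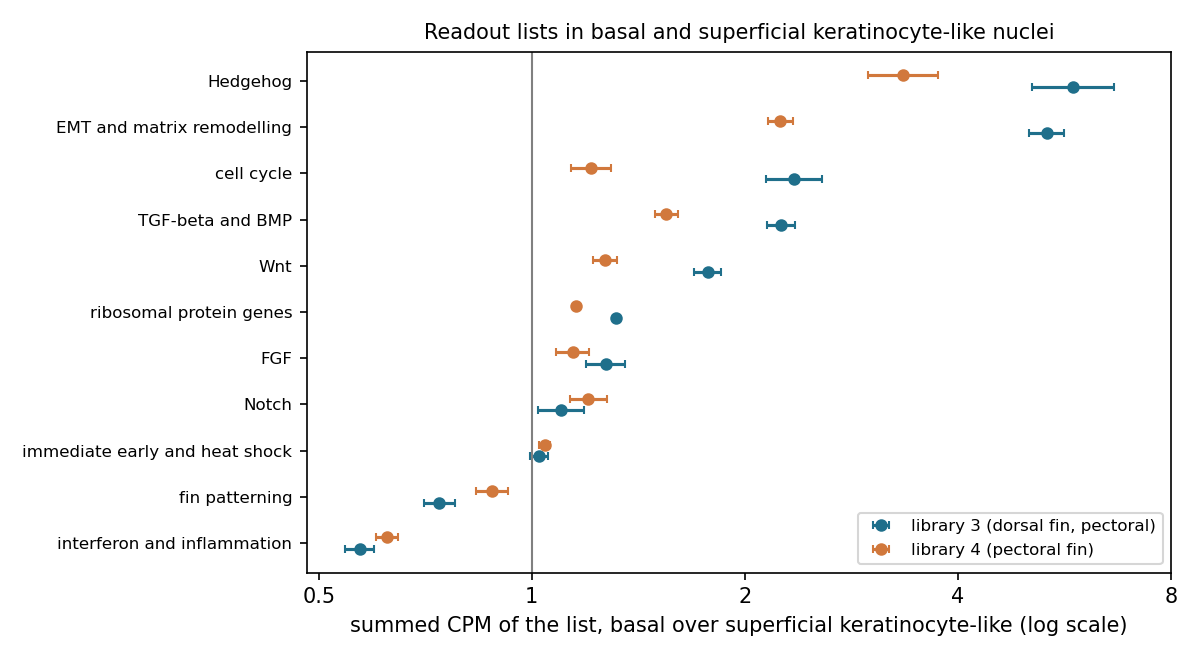
Ratio of the summed CPM of each list in basal over superficial keratinocyte-like nuclei (x axis, log scale) in each library, with exact 95% intervals for counting error. Hedgehog (5.81 and 3.35) and transition and matrix genes (5.34 and 2.25) lie farthest toward basal nuclei in both libraries, and interferon and inflammation genes lie toward superficial nuclei in both.

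The lists were then set side by side over all named classes of at least 200 nuclei. The transition and matrix, Wnt, TGF-beta and BMP, Hedgehog and fin patterning lists were highest in fibroblast-like nuclei of library 3, at 3483, 2885, 2329, 1067 and 1446 CPM. There sparc, a matrix protein gene, stood at 585 and 506 CPM for its copies (ENSSSAG00000056353 and ENSSSAG00000065629) and loxl2a (ENSSSAG00000081119), a collagen crosslinking enzyme, at 219 CPM. The Wnt effectors tcf7l2 (ENSSSAG00000077505 and ENSSSAG00000066753, 468 and 240 CPM) and tcf7 (ENSSSAG00000006857, 179 CPM), tgfbr3, a TGF-beta co-receptor (ENSSSAG00000010024 and ENSSSAG00000035831, 686 and 128 CPM), ltbp1 (231 CPM), and the Hedgehog genes gli3 (ENSSSAG00000070213), cdon and boc (321, 177 and 144 CPM) were the most abundant members of their lists there. Of the fin patterning genes meis2a, tbx15 (ENSSSAG00000063496) and sall1a (ENSSSAG00000069795), transcription factor genes all, stood highest there at 161, 155 and 117 CPM. Notch genes peaked in endothelial-like nuclei of library 3 at 732 CPM, with the vascular ligand dll4 (ENSSSAG00000055522) at 127 CPM, lfng (ENSSSAG00000113402) at 79.2 CPM and rbpj (ENSSSAG00000003166) at 63.6 CPM. FGF genes peaked in basal nuclei of library 3 at 744 CPM, with both copies of the receptor fgfr2 (ENSSSAG00000054894 and ENSSSAG00000056070) at 315 and 175 CPM and dusp6 (ENSSSAG00000004251), a feedback phosphatase, at 82.0 CPM. Interferon and inflammation genes peaked in mucous cell-like nuclei of library 3 at 1705 CPM, led by both copies of stat1a (ENSSSAG00000102446 and ENSSSAG00000056374, 472 and 423 CPM) and by stat3 (ENSSSAG00000010060, 105 CPM). The interval of that sum (1602 to 1814) overlapped that of superficial nuclei of library 4, at 1654 CPM (1618 to 1690). Mucous cell-like nuclei of library 4 stood lower, at 1384 CPM. The heat shock list and the ribosomal protein genes peaked in library 4, in keratinocyte-like nuclei without a clear layer, at 6019 and 58780 CPM, with the chaperones hspa8 (ENSSSAG00000049191) at 1753 CPM and both copies of hsp90ab1 (ENSSSAG00000040057 and ENSSSAG00000002480) at 1723 and 417 CPM. Droplets without a nucleus of library 4 held more of both lists, 7889 and 95570 CPM. With free RNA subtracted hspa8 fell to 1084 CPM in these nuclei. The ribosomal sum of the class then stood at 33630 CPM in library 4 against 46680 CPM in library 3, so its peak in library 4 holds only before subtraction.

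Dividing nuclei were sought among the keratinocyte layers. After every nucleus had been thinned to 1500 UMIs, 15.9% (13.6 to 18.6) of 860 basal nuclei of library 3 and 12.4% (10.8 to 14.1) of 1549 basal nuclei of library 4 held UMIs from at least 2 cell cycle genes. Among superficial nuclei 4.31% (2.86 to 6.21) of 626 and 9.0% (7.65 to 10.5) of 1634 did. Fibroblast-like nuclei reached 6.97% (5.07 to 9.30) and 8.67% (4.93 to 13.9). The keratinocyte-like remainder stood above basal nuclei in library 3, at 21.2% (19.0 to 23.6), and overlapped them in library 4, at 13.3% (12.6 to 14.0). Endothelial-like nuclei reached 8.72% (4.73 to 14.5) and 12.04% (6.57 to 19.7), and mucous cell-like nuclei 4.1% (1.79 to 7.92) and 11.65% (6.17 to 19.5). In library 4 both thus lay near basal nuclei. The summed cell cycle list gave the same order of layers, 545 CPM (520 to 571) in basal against 232 (214 to 250) in superficial nuclei of library 3 and 424 (406 to 443) against 349 (333 to 366) in library 4. Droplets without a nucleus held this list at 620 CPM in library 3 and at 545 CPM in library 4. In each library that was above both basal and superficial nuclei. The list peaked at 664 CPM (672 CPM with free RNA subtracted) in the keratinocyte-like remainder of library 3, whose name rests largely on exclusion. There both copies of diaph3 (ENSSSAG00000084823 and ENSSSAG00000091681), which acts in cell division, stood at 59.5 and 57.3 CPM and the replication gene mcm3 (ENSSSAG00000055449) at 49.8 CPM. Of 27 cell cycle genes with at least 20 UMIs in each library, 20 were higher in basal nuclei of both. Among them were the condensin gene ncapg (ENSSSAG00000102996) at 8.38-fold (3.02 to 32.3) and 2.44-fold (1.16 to 5.50), the mitotic gene birc5a (ENSSSAG00000001277) at 1.99-fold (0.82 to 5.28) and 2.20-fold (1.29 to 3.85) and the spindle gene prc1b (ENSSSAG00000051948) at 3.18-fold (1.14 to 10.95) and 1.90-fold (0.92 to 4.09).

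Free RNA alone, at the median depth of each class, would give at least 2 cell cycle genes in 1.97% and 4.43% of basal nuclei. It would do so in 0.92% and 4.45% of superficial nuclei and in 4.82% and 6.27% of fibroblast-like nuclei. For the keratinocyte-like remainder the values were 1.7% and 5.22%. In library 4 they were 6.17% for endothelial-like and 6.3% for mucous cell-like nuclei. Most of the fibroblast-like share and part of the superficial share of library 4 thus lie within background. For library 3 these medians (1252 UMIs for fibroblast-like nuclei) take in the shallower nuclei that thinning left out. The background of library 3 is therefore set too high, and how much of its fibroblast-like share it makes up cannot be told. Thinning left out 342 basal, 77 superficial and 1234 of 1837 fibroblast-like nuclei of library 3 and none of these classes in library 4, and unthinned shares were 24.9% and 27.4% of basal and 17.4% and 21.7% of superficial nuclei.

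The next comparison was between the libraries within a class, with genes named by a fixed rule. In all nuclei the AP-1 subunit gene fosb (ENSSSAG00000102772) was 22.8-fold (18.7 to 28.02) higher in library 4, gadl1 (ENSSSAG00000057034), an amino acid decarboxylase gene, 14.0-fold (12.1 to 16.2) and tenm4 (ENSSSAG00000101378), a teneurin gene, 12.6-fold (10.1 to 15.98). TTN was higher in library 3, 168-fold (ENSSSAG00000119643, 121 to 242) and 114-fold (ENSSSAG00000095939, 90.7 to 145), and hspa12a (ENSSSAG00000075965), of the heat shock protein family, 53.5-fold (40.5 to 72.2). The 31 skeletal muscle-like nuclei held 2198 of the 2879 and 3133 of the 4227 TTN UMIs of library 3, in that order of copies. In basal nuclei ndufa4l2b (ENSSSAG00000120770), a mitochondrial gene known to respond to low oxygen, was 40.1-fold (15.4 to 148) higher in library 4, amt (ENSSSAG00000066884) of the glycine cleavage system 33.7-fold (14.2 to 105) and fosb 30.7-fold (17.4 to 59.7). In the other direction basal nuclei had 182 UMIs of hspa12a in library 3 against 1 in library 4, a ratio of 265 (46.9 to 10510), and TTN at 117-fold (ENSSSAG00000095939, 45.1 to 431) and 61.7-fold (ENSSSAG00000119643, 26.0 to 192). In superficial nuclei MDK (ENSSSAG00000105878), the growth factor midkine, was 26.0-fold (11.8 to 71.4), fosb 25-fold (14.8 to 46.0) and gadl1 21.3-fold (12.6 to 39.3) higher in library 4. The glycine transporter gene slc6a9 (ENSSSAG00000053438) was 76.0-fold (45.0 to 140) higher in superficial nuclei of library 3, the ubiquitin ligase gene peli1b (ENSSSAG00000118555) 7.93-fold (5.70 to 11.3) and mdga2a (ENSSSAG00000078395) 7.42-fold (5.16 to 10.9).

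Several of these genes differed as much in droplets without a nucleus, where fosb stood at 6.28 CPM in library 3 and 119 CPM in library 4, and TTN (ENSSSAG00000095939) at 174 and 1.59 CPM; MDK (21.0 and 116 CPM) and gadl1 (11.6 and 158.5 CPM) stood there above their levels in superficial nuclei of both libraries, and with free RNA subtracted MDK in superficial nuclei of library 3 and hspa12a in basal nuclei of library 4 fell to 0, against 21.1 and 56.2 CPM in the other library, so that no fold could be given. Basal nuclei came mostly from cluster 7 in library 3 and cluster 5 in library 4, and superficial nuclei from clusters 9 and 4, so a library and a state of these cells could not be separated; over the other settings with a UMI in both libraries the basal folds ran from 135.6 to 274.6 for hspa12a, 42.9 to 214 (ENSSSAG00000095939) and 25.4 to 114.5 (ENSSSAG00000119643) for TTN, 14.3 to 78.5 for ndufa4l2b and 25.01 to 63.6 for fosb, and those of fosb in superficial nuclei from 17.4 to 37.9, while at Leiden resolution 0.5 hspa12a and TTN had 0 UMIs in basal nuclei of library 4 and folds of at least 7.48 (hspa12a), 13.15 and 8.71 (TTN).

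As groups, stress genes were higher in library 4 in the classes compared, and fin patterning genes were higher in library 3 in most of them. Immediate early and heat shock genes were higher in library 4 in basal (1.70-fold, 1.66 to 1.74), superficial (1.66-fold, 1.62 to 1.71), fibroblast-like (1.64-fold, 1.57 to 1.72), endothelial-like (1.52-fold, 1.43 to 1.62) and mucous cell-like nuclei (1.93-fold, 1.80 to 2.07). In the keratinocyte-like remainder, the largest class of both libraries, the list stood at 4706 CPM in library 3 and 6019 CPM in library 4. With free RNA subtracted it stood there at 4468 and 4741 CPM, so little of the difference was left. This class had not passed the check of top genes. In library 3 it joined cluster 6 (1509 nuclei, median 2909 UMIs) with shallow clusters such as 8.0 (193 nuclei, median 978 UMIs). Its sums thus compare unlike mixtures of nuclei. In basal nuclei 38 of 47 members with at least 10 UMIs were higher in library 4. The list's median log2 ratio of 0.66 lay above those of all but a negligible part of 10000 random lists of like expression (percentile 100.0). The ribosomal and the interferon and inflammation lists reached the same percentile in basal nuclei. The interferon fold there fell to 0.996 with free RNA subtracted. The random lists were not matched on free RNA, so this percentile cannot tell free RNA from expression in the nuclei. Ribosomal protein genes were 1.89-fold (1.88 to 1.91) and 2.16-fold (2.14 to 2.18) higher in basal and superficial nuclei of library 4. In the keratinocyte-like remainder they stood at 51510 CPM in library 3 and 58780 CPM in library 4. With free RNA subtracted the direction turned there, with 46680 CPM in library 3 and 33630 CPM in library 4. Ribosomal protein genes were among the top genes of its clusters 8.4 and 8.7 in library 3, so its unlike make-up bears on this turn. Hedgehog genes were higher in library 3, 1.92-fold (1.78 to 2.07) in basal and 2.67-fold (2.29 to 3.13) in fibroblast-like nuclei, and in superficial nuclei the ratio was 1.104 (0.94 to 1.30). With free RNA subtracted the first 2 folds were 1.57 and 2.29. Markers of these classes were lower in library 4 as well. The fibroblast list was 3.50-fold (3.37 to 3.63) higher in fibroblast-like nuclei of library 3. In basal nuclei DST stood at 3616 CPM in library 3 and 1246 CPM in library 4, and ITGA6 at 1498 and 731.5 CPM. A less pure class in library 4 thus cannot be told apart from a difference in the lists that were higher in library 3. The transition and matrix list was 1.68-fold (1.63 to 1.73) higher in basal nuclei of library 3 but its sum was 1.42-fold (1.33 to 1.51) higher in superficial nuclei of library 4, where only 19 of 37 members were higher in library 4 and the median log2 ratio was 0.02. Cell cycle genes were 1.29-fold (1.204 to 1.37) higher in basal nuclei of library 3 and 1.51-fold (1.38 to 1.65) higher in superficial nuclei of library 4.

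Wnt, TGF-beta and BMP, and FGF genes were 1.48-fold (1.43 to 1.54), 1.42-fold (1.37 to 1.47) and 1.28-fold (1.21 to 1.35) higher in basal nuclei of library 3, although the median FGF gene went the other way (log2 ratio of 0.24). Notch genes differed there by 1.03-fold (0.97 to 1.101) and interferon and inflammation genes were 1.16-fold (1.104 to 1.21) higher in library 4. With free RNA subtracted the interferon ratio in basal nuclei fell to 0.996, the ribosomal ratio in superficial nuclei was 1.24, and the heat shock ratios were 1.51 in basal and 1.30 in superficial nuclei. Scaling by trimmed mean of M values raised log2 ratios of library 4 over library 3 by 0.34 in all nuclei, 0.19 in basal and 0.17 in superficial nuclei.

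The fins differ in position along the body, so genes that pattern fins were compared by name. Of 78 matched gene copies 71 had a UMI, 23 passed the minimum and the 12 most abundant are given. For fibroblast-like nuclei (1837 in library 3 and 173 in library 4), endothelial-like and mucous cell-like nuclei that minimum counted library 3 only. Genes of these classes that were higher in library 4 were less able to pass. The directions of the 12 therefore do not show which way the list leans. The transcription factor gene zic1 (ENSSSAG00000044953), known from dorsal structures, had 376 UMIs in nuclei of library 3 and 0 in library 4, at least 256-fold higher against a floor of 3 counts. In fibroblast-like nuclei it had 293 against 0, at least 14.9-fold. Its other copy (ENSSSAG00000066730) was 43.4-fold (23.1 to 91.7) higher in library 3. Among posterior Hox genes hoxc11a (ENSSSAG00000077471) was 29.9-fold (17.7 to 54.3) higher in library 3, and hoxb9a (ENSSSAG00000121194) had 133 UMIs against 2, a ratio of 136 (36.9 to 1135). Both copies of tbx15 (ENSSSAG00000063496 and ENSSSAG00000059227), a T-box gene of trunk mesenchyme and skin, were 19.4-fold (14.8 to 25.6) and 14.0-fold (10.6 to 18.7) higher in library 3 over all nuclei, and 4.77-fold (2.81 to 8.80) and 3.63-fold (2.05 to 7.11) in fibroblast-like nuclei. The limb patterning genes lmx1bb (ENSSSAG00000054097), msx1a (ENSSSAG00000055769) and meis2a were 5.32-fold (4.90 to 5.77), 4.05-fold (3.36 to 4.91) and 1.97-fold (1.88 to 2.08) higher in library 3. In contrast hoxc6a, a Hox gene of more anterior trunk levels, was 1.81-fold (1.63 to 2.01) higher in library 4, and meis2 and sall1a were higher in library 3 by only 1.19-fold (1.14 to 1.23) and 1.14-fold (1.08 to 1.204).

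Members outside that rule, chosen after their values were seen, included the pectoral limb gene tbx5a. A copy of it (ENSSSAG00000098747) had 0 UMIs in library 3 against 82 in library 4 (at least 13.4-fold), and the other copy (ENSSSAG00000051541) 3 against 61 (9.94-fold, 3.25 to 49.5). In fibroblast-like nuclei of library 4, which the rule did not count, these copies had 25 and 12 UMIs. Copies of EN1 (ENSSSAG00000111087 and ENSSSAG00000100497), a gene of ventral limb ectoderm, had 4 against 253 (30.9-fold, 11.9 to 114) and 0 against 65 (at least 10.6-fold). HOXC10 (ENSSSAG00000066783, 115 against 3 UMIs, a ratio of 78.4, 26.2 to 386) and zic4 (ENSSSAG00000044903, 124 against 1, a ratio of 254, 44.7 to 10100) went with library 3. So did hand2 (ENSSSAG00000106585, 115 against 33, 7.13-fold, 4.80 to 10.8). A copy of tbx4 (ENSSSAG00000051701, 13 against 62, 2.33-fold, 1.27 to 4.62) and pitx1 (ENSSSAG00000067385, 46 against 155, 1.65-fold, 1.18 to 2.34) were higher in library 4. The other copy of tbx4 (ENSSSAG00000053630) had 28 against 47, a ratio of 1.22 (0.73 to 1.99) toward library 3. These picked members do not show whether the list sorts by fin label. Of the 50 gene copies of the list with at least 20 UMIs over both libraries, 26 were at least 4-fold higher in library 3, 5 were at least 4-fold higher in library 4 and 19 lay between. As a whole the list was 1.63-fold (1.59 to 1.66) higher in library 3 over all nuclei, 1.63-fold (1.55 to 1.72) in basal and 1.94-fold (1.84 to 2.04) in superficial nuclei. It was 1.52-fold (1.37 to 1.69) higher in fibroblast-like and 1.45-fold (1.19 to 1.79) in endothelial-like nuclei. In mucous cell-like nuclei the ratio was 1.056 (0.86 to 1.31), and 0.852 with free RNA subtracted. In superficial nuclei of library 3 meis2 alone held 1804 of the 3352 UMIs of the list. Fibroblast-like nuclei, which held most zic1 and tbx15 UMIs, were far fewer in library 4. Reads shared between near-identical salmon gene copies may be split between them in ways that these counts do not show.

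**Figure D4:**
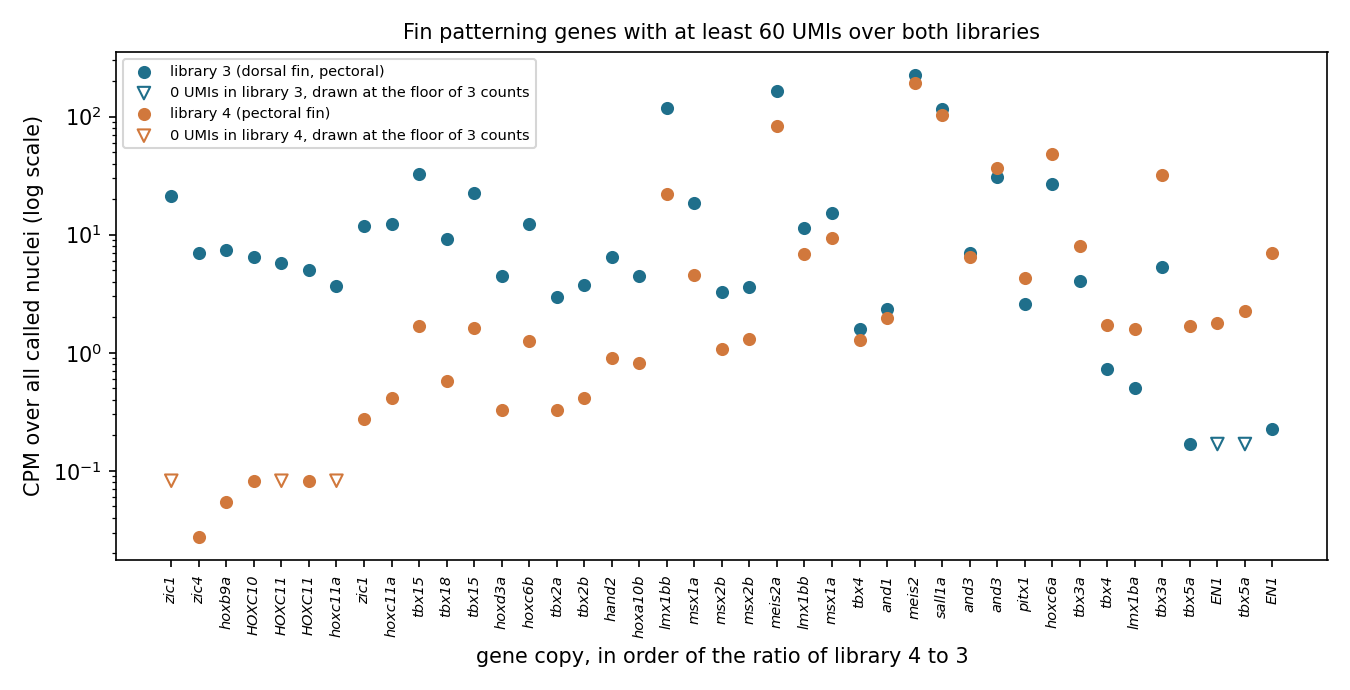
CPM over all called nuclei (y axis, log scale) of the 41 fin patterning gene copies with at least 60 UMIs over both libraries, in the order of the ratio of library 4 to library 3; open triangles stand for 0 UMIs and are drawn at the floor of 3 counts. Copies of zic1, zic4, hoxb9a and HOXC10 lie at the library 3 end and both copies of tbx5a and EN1 at the library 4 end.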

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

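All tests in this part were chosen after the results they examine had been seen. Signals were sought in the droplets without a nucleus, which lie outside the main measurement, against the limit that a count of 0 allows. No nucleus of library 4 was T cell-like, yet its droplets without a nucleus held the T or NK cell marker list at 476.3 CPM (470 to 483), against 684 CPM in library 3 and a limit of 0.072 CPM, which any expressed list would pass. Among the most abundant list genes there were both copies of runx3 (ENSSSAG00000064246 with 6589 UMIs and ENSSSAG00000003444 with 5935), BCL11B (ENSSSAG00000045088, 2592 UMIs) and cd3e (ENSSSAG00000076824, 552 UMIs). In nuclei of library 4 runx3 stood at 148.5 and 190 CPM for these copies, against 159 and 143 CPM in the droplets, BCL11B at 80.7 against 62.5 CPM and cd3e at 7.01 against 13.3 CPM, so runx3 and BCL11B were not limited to T cell-like nuclei, and whether T cells added to the RNA in the droplets was not tested. The skeletal muscle list stood at 46.46 CPM (44.4 to 48.6) in the same droplets of library 4, against 566 CPM in library 3, with 1042 of its 1926 UMIs from actn3b (ENSSSAG00000054628), although no nucleus of library 4 was muscle-like.

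The first pattern weighed was the difference in fin patterning genes, with 26 gene copies at least 4-fold higher in library 3 and 5, of tbx5a, tbx3a and EN1, at least 4-fold higher in library 4. A lower depth of library 3 is argued against for those 5 copies by the droplets without a nucleus: at the rate of library 4, 1182.4 UMIs were expected in library 3 and 137 (115 to 162) were seen. These droplets were not used to choose the copies. The same free RNA is part of the counts of nuclei that were, so the test is not independent of the choice. A copy of tbx3a (ENSSSAG00000045305) held 1302 of the 1985 UMIs in library 4 and 124 of the 137 in library 3. Fewer or less pure fibroblast-like nuclei in library 4 cannot be told apart from it for the 26 copies together, since inside that class they were 4.734-fold (3.80 to 5.97) higher where the fibroblast markers as a list were 3.50-fold (3.37 to 3.63) higher. With limits widened for 26 tests only zic1 (ENSSSAG00000044953, 293 UMIs against 0, at least 6.37-fold) passed that list, and a single marker, postnb (ENSSSAG00000081731), was itself 10.86-fold (6.56 to 19.5) higher, while copies singled out after their values were seen differed mostly outside the class, where, free RNA aside, fewer fibroblast-like nuclei do not reach: lmx1bb (ENSSSAG00000054097, 385 UMIs against 56 in basal nuclei), hoxc6b (ENSSSAG00000121322, 220 against 46 in all nuclei and 9 against 4 in the class), HOXC11 (ENSSSAG00000081138, 103 against 0 and 7 against 0) and hoxb9a (ENSSSAG00000121194, 133 against 2 and 28 against 0). A difference between fins by position along the body and the amount of pectoral tissue in library 3 remain open and untested, since each fin label has 1 library, although the copies of tbx5a had 0 and 0 UMIs in 1837 fibroblast-like nuclei of library 3 against 25 and 12 in 173 of library 4, and 0 and 7 against 97 and 79 in the droplets without a nucleus.

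The second pattern was the lower fibroblast-like share of library 4, 1.32% against 24.3%. The higher calling threshold of library 4 is argued against as its cause, since 14.3% (13.2 to 15.5) of the nuclei of library 3 past that threshold were still fibroblast-like. Loss of such nuclei in calling or naming as the whole cause is argued against by the droplets without a nucleus, where the fibroblast marker list was 3.449-fold (3.43 to 3.47) higher in library 3, although the shares differed by 18.5-fold and part of the gap is left open. How the piece of skin was taken, how many nuclei each cell type released and a difference between the fins remain open and untested.

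The last pattern was the higher level of immediate early and heat shock genes in library 4. With free RNA subtracted the list was still higher in library 4 in all 5 classes compared, by 1.304-fold to 1.89-fold. In the keratinocyte-like remainder, outside that test and made of unlike clusters in the libraries, it then stood at 4468 CPM in library 3 and 4741 CPM in library 4. Ribosomal protein genes, abundant in the droplets without a nucleus (95570 CPM in library 4), also stayed higher after subtraction, by 1.238-fold to 3.405-fold in the 5 classes. Subtraction may thus leave free RNA behind, so free RNA as the whole source is not settled. A single abundant gene is argued against, since without hspa8 (ENSSSAG00000049191) the list was still 1.584-fold higher in superficial and 1.61-fold higher in basal nuclei. Handling of the tissue before nuclei were released, which the labels do not describe per library, and a difference between the fins remain open and were not tested.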

How the results depend on the processing

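The calling rule of the design, calling at 4 SD, leaving out 10% of nuclei by doublet score, skipping sub-clustering, thinning to 1100 UMIs and free-RNA subtraction were chosen as alternatives after the data were seen, and the others before. No paired analysis was possible because each group has 1 library. The fibroblast-like share stayed higher in library 3 and the keratinocyte-like share (51.7% in library 3 and 95.5% in library 4) higher in library 4 at every setting that gave a value, as did the immediate early and heat shock list in basal and superficial nuclei of library 4, and the transition and matrix list stayed higher in basal than in superficial nuclei. In the order keratinocyte-like of library 3 and 4, then fibroblast-like of library 3 and 4, the percentages that moved were as follows. At Leiden resolution 0.5 they were 59.71, 85.0, 16.49 and 6.26; at 2.0, 38.68, 94.53 and, for fibroblast-like of library 3, 17.13. With 4000 variable genes library 3 had 44.22 and 25.97; with genes scaled within each library keratinocytes had 55.47 and 92.41 and fibroblasts of library 4 had 2.55. With each library clustered on its own they were 46.38, 98.46, 17.35 and 0.71; with readout lists kept among the variable genes 46.72, 95.88 and, for fibroblasts of library 4, 0.65, which another clustering seed put at 1.57. The calling rule of the design gave 72.56, 99.11, 10.64 and 0.53 with 47658 barcodes in library 4. At least 500 UMIs gave 50.26, 53.61, 47.12 and 0.67 with 29991 and 59313 barcodes. At least 1000 UMIs gave 69.31, 93.91, 19.76 and 0.56 with 43743 barcodes in library 4. The 7000 barcodes with the most UMIs gave keratinocytes 48.29 and 81.97 and fibroblasts of library 4 0.23, with 7000 barcodes called in library 4. Calling at 4 SD gave 58.64, 96.29, 22.96 and 1.06. Without the nuclei of highest doublet score they were 45.72, 95.12, 25.32 and 0.95. Without sub-clustering keratinocytes of library 3 had 45.65 and fibroblasts of library 4 had 0.03. For the immediate early and heat shock list the folds of library 4 over 3 in basal and superficial nuclei moved to 1.545 and 1.756 at resolution 0.5, 1.582 and 1.939 at 2.0, 1.533 and 1.964 with each library clustered on its own, 1.94 and 1.872 with TMM scaling, and 1.513 and 1.304 with free RNA subtracted. In basal nuclei the 7000 barcodes gave 1.519; in superficial nuclei the calling rule of the design gave 1.933, at least 500 UMIs 1.804, at least 1000 UMIs 1.721, 4 SD 1.623, and leaving out genes whose empty droplets differ as much 1.608. The transition and matrix ratio of basal over superficial nuclei moved in library 3 to 4.984 with scaled genes, 5.013 with the calling rule of the design, 6.446 without the highest doublet scores, 2.176 as mean log2 CPM per gene and 9.886 with free RNA subtracted. In library 4 it moved to 3.103 and 2.446 at resolutions 0.5 and 2.0, 2.361 with each library on its own, 2.377 with the calling rule of the design, 2.543 without the highest doublet scores, 1.474 as mean log2 and 4.287 with free RNA subtracted. The cycling share of basal nuclei moved to 20.67% in library 3 at resolution 2.0, 20.82% with each library on its own and 21.41% with 7000 barcodes, and to 9.28% in library 4 at resolution 0.5. For basal nuclei of library 3 and 4 and superficial nuclei of library 3 and 4 it was 40.23%, 43.83%, 27.32% and 41.55% with at least 1 cell cycle gene, 7.33%, 3.42%, 1.12% and 2.08% with at least 3, and 24.88%, 27.44%, 17.35% and 21.73% without thinning. Thinned to 1100 UMIs it was 11.75% and 8.52% in basal nuclei and 5.63% in superficial nuclei of library 4. Some directions turned. Basal over superficial nuclei, the immediate early list of library 4 turned to 0.9003 at resolution 0.5 and 0.9981 as mean log2, and ribosomal protein genes of library 4 to 0.9742 at 0.5. Notch of library 3 turned to 0.9621 as mean log2 and 0.9892 without the gene with the most UMIs, FGF of library 3 to 0.8969 without that gene, and fin patterning to 1.063 and 1.012 as mean log2 and 1.284 and 1.224 without that gene. For library 4 over 3, the cell cycle list in all nuclei turned to 1.031 with the calling rule of the design and again with at least 1000 UMIs, to 1.175 with TMM and to 1.159 without genes whose empty droplets differ as much. FGF in all nuclei turned to 1.134 with TMM, Wnt in superficial nuclei to 1.059 with TMM and 1.03 with free RNA subtracted, and interferon in basal nuclei to 0.9957 with free RNA subtracted. The cause was not tested. Of the other list and gene values between libraries 597 stayed within their interval, 181 moved beyond it (3 of them only limits, from 0 UMIs in library 4) and 8 turned, as given above. Of the other ratios between basal and superficial nuclei 195 stayed, 95 moved and 10 turned. A value was counted as turned only where its main interval left out 1, so some that moved also changed sides. Notch genes in all nuclei were 1.005-fold (0.98 to 1.03) higher in library 3 but up to 1.261-fold higher in library 4 at another setting. Of the other class shares 67 stayed and 53 moved, and of the other cycling shares 47 stayed and 23 moved. With a minimum of 10 UMIs and no CPM minimum 0, 4 and 1 of the genes named in all, basal and superficial nuclei would still be named, and without genes whose empty droplets differ as much 5 in each. No basal class was found with at least 500 UMIs, too few basal nuclei in library 4 with at least 1000, and no superficial class in library 4 with the 7000 barcodes, so ratios that need them have no value there, and keeping doublets tested nothing, since none was called. The cycling share rose with depth in basal nuclei of both libraries, from the thinned values at 1100 UMIs to those at 1500 UMIs (15.93% and 12.4%) and those without thinning.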

Other observations

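Several genes named for basal or superficial nuclei differed between the libraries in other cell types as well; the values in this part were chosen after the data were seen. The glycine transporter gene slc6a9 had 124 UMIs (209 CPM) in mucous cell-like nuclei of library 3 and 0 in those of library 4, with 40.7 and 2.53 CPM in droplets without a nucleus. The heat shock family gene hspa12a stood at 156 CPM in fibroblast-like and 267 CPM in endothelial-like nuclei of library 3, against 37.0 and 29.9 CPM in library 4 and 59.98 and 1.21 CPM in the droplets. The ubiquitin ligase gene peli1b was at 194 CPM in basal and 164 CPM in endothelial-like nuclei of library 3, against 10.1 and 3.74 CPM in library 4 and 57.3 and 6.80 CPM in the droplets. For gadl1 the droplets held 11.6 CPM in library 3 and 158.5 CPM in library 4, at or above its level in fibroblast-like (2.83 and 141 CPM), endothelial-like (5.66 and 112 CPM) and mucous cell-like nuclei (6.75 and 156 CPM), so expression in these classes cannot be read from the counts.

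The small osteoblast-like class (105 nuclei in library 3 and 76 in library 4) carried more of the transition and matrix list than any class of 200 nuclei or more in the same library, with 5203 and 3164 CPM, and FGF genes at 1492 and 822 CPM. Among the unnamed nuclei, cluster 11 held 271 nuclei of library 3 and 102 of library 4, with pcdh11 (ENSSSAG00000057824), a protocadherin gene, among its top genes in both libraries and a further copy (ENSSSAG00000058286) in library 3. By its nuclei of library 4 alone it would be named leukocyte-like, with 3 of 5 detected leukocyte markers 2-fold above all nuclei of that library, while in library 3 no list named it. In library 4 its top genes also included PLCB1 (ENSSSAG00000067988), alk (ENSSSAG00000009062) and ARHGAP9 (ENSSSAG00000046609). In droplets without a nucleus the marker lists of endothelial cells, neurons, osteoblasts and chondrocytes were 4.43-fold, 3.73-fold, 3.41-fold and 2.95-fold higher in library 3, mucous cell markers 1.76-fold and epithelial markers 1.21-fold, while the ratios of library 3 to library 4 were 0.74 for ionocyte, 0.74 for erythrocyte and 0.75 for thrombocyte markers.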
